A study of Mus musculus with 17 samples.

How the data were processed

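Small RNA libraries of the mouse ESC lines B8 and D3 were analysed from the miRNA table of the study. Its values are signal, as deposited by the authors: reads per mature miRNA divided by a factor for each library, with TMM named as the normalization by the table's title. These factors disagree with TMM over the miRNA rows, under which the column totals of the 14 libraries would differ up to 2.69-fold, against 17.7-fold as deposited. The rows and library sizes behind the deposited factors are not known. The authors' notes name CASAVA, FastQC, Bowtie, Partek and the mm10 genome without versions or settings, and the column titles name cutadapt and a length step. Rules for counting reads that match several miRNAs are not stated. Values of identical or near-identical members, such as miR-199a-3p and miR-199b-3p or the members of the Sfmbt2 cluster, are therefore uncertain one by one. Each such entry was still counted as its own member of a list. In every library 100% of the low values, up to 1000 reads, were whole multiples of a single value to within 0.01 of a read. This recovered whole reads. The column totals ran from 46965.1 to 830401.5 and the recovered miRNA reads from 56377 to 1060306, so the deposited values share no common total.

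Of 17 labelled samples in 6 groups, for which the tests had been laid out, 14 in 5 groups entered the fit. The 3 samples of B8 at day 21 were not analysed here, and 7 of the 11 planned comparisons were made. D3 at day 7 has replicates 2 and 3. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

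Recovered miRNA reads per sample numbered 138397 to 275271 in B8 at day 0 and 141823 to 256613 in B8 at day 7. They numbered 56377 to 129486 in D3 at day 0, 1008438 to 1060306 in D3 at day 7 and 547213 to 743039 in D3 at day 21. Total reads per library, and so the sequencing depth, are not given here. The value of 3 reads, taken as the floor for each library and averaged over a group, was 2.01, 2.72, 1.89, 2.25 and 1.02 in that order. Folds against a group at 0 in all libraries were computed against this floor. Such floors cover counting error only, since reads copied by PCR are not independent molecules.

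Of 1033 miRNAs, 521 with a mean of at least 5 per 1000000 of the column total were kept. Values were analysed as log2 of the value plus a pseudocount of 0.48, which is 2 per 1000000 of the mean column total. A limma model (version 3.58.1, R 4.3.3) of 5 group means with a trended prior and 9 residual degrees of freedom gave 2-sided moderated tests, and p-values were adjusted over all kept miRNAs by Benjamini-Hochberg with a threshold of 0.05. The difference between the lines in the change from day 0 to day 7 was tested as an interaction. Tested on simulated data with 20 simulations, the B8 comparison of days 7 and 0 recovered 17.9%, 50.7% and 85% of changes of 1.5-fold, 2-fold and 4-fold with 4.81% false calls, and the D3 comparison 12.9%, 39.9% and 79.4% with 4.21%. Each simulation changed 200 miRNAs, as many up as down, with otherwise equal means in all groups and with the library factors known. These rates hold for that setting and do not cover errors of scaling or a shift common to most miRNAs.

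The 17 lists of miRNAs were fixed before the data were examined, as were the tests, the rule for naming miRNAs and the other settings to be tried. They are the miR-290, miR-302, miR-17-92 and miR-183 clusters, the let-7, miR-99 and miR-125 and miR-34 and miR-449 families, Hox-embedded miRNAs, the Dlk1-Dio3 region, the Sfmbt2 intron cluster (a list by name, with some precursors annotated on other chromosomes), markers of neural, muscle, mesenchymal, epithelial, endodermal, and blood and endothelial cells, and entries that resemble fragments of rRNA or tRNA. Each list was tested against the other miRNAs with camera at a preset correlation of 0.01, adjusted over the 17 lists of a comparison, and again with an estimated correlation. Camera compares a list with all other miRNAs, so its direction can differ in sign from the list's median when most miRNAs shift. Shared calls of the lines were tested with Fisher's exact test. Named miRNAs were, for each comparison, the 5 with the largest changes each way among those past the threshold, above the median level and without overlap of samples, up to 3 of the most abundant members of each list past the threshold, and up to 2 of the let-7, miR-290 cluster, miR-302 cluster, neural, muscle and Dlk1-Dio3 lists. For the interaction they were the 5 with the smallest adjusted p each way, and the 5 most abundant miRNAs of each group were named for the description of the data.

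The settings laid out beforehand were pseudocounts of 0.2 and 10 per 1000000, no filter and a filter at 50 per 1000000, equal column totals, median-of-ratios factors over the 319 miRNAs above 0 in all libraries, a prior without trend, the compared groups alone, a block for replicate number, and leaving out each replicate in turn. Chosen after seeing the data were equal totals without miR-10a and miR-10b, and edgeR (version 4.0.16) quasi-likelihood tests on the recovered reads with the authors' factors or with TMM factors over the miRNAs. Positions of precursors are those of GRCm38.p6, the build that mm10 names. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.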

Results

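Small RNA sequencing was used to follow the miRNomes, the sets of expressed microRNAs (miRNAs), of 2 mouse embryonic stem cell (ESC) lines, B8 and D3, during differentiation. ESCs are pluripotent cells derived from the early embryo, and LIF is the cytokine that keeps them undifferentiated in culture. Day 0 samples were undifferentiated ESCs grown with LIF and without feeder cells. Day 7 samples were embryoid bodies, spherical aggregates of differentiating cells formed in hanging drops, and day 21 samples were outgrowths of such bodies. From the start of differentiation the medium lacked LIF and contained retinoic acid, a mix of insulin, transferrin and selenium, and the N2 supplement. Values were analysed for 14 libraries: 3 of B8 at day 0, 3 of B8 at day 7, 3 of D3 at day 0, 2 of D3 at day 7 and 3 of D3 at day 21. B8 at day 21 (3 samples) was not analysed here, so 4 of the 11 planned comparisons could not be made: B8 day 21 against day 0 and against day 7, D3 against B8 at day 21, and the difference between the lines in the change to day 21.

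The libraries held between 56377 and 1060306 miRNA reads. In undifferentiated cells of both lines the most abundant miRNA was miR-182-5p, of a cluster on chromosome 6, with 15.97% ± 0.131 of the miRNA signal in B8 and 13.8% ± 1.25 in D3 (SD, n = 3 each). It was followed in B8 by miR-295-3p (11.03% ± 1.20) and miR-292a-5p (7.86% ± 0.72), both of the ESC-specific miR-290 cluster, miR-127-3p of the imprinted Dlk1-Dio3 region (6.79% ± 0.336) and miR-22-3p (4.97% ± 0.175). The same 5 miRNAs led in D3 at day 0, where miR-127-3p had 13.5% ± 0.73, miR-295-3p 9.22% ± 1.06, miR-292a-5p 5.86% ± 1.01 and miR-22-3p 3.74% ± 0.322. By day 7 miR-10a-5p and miR-10b-5p, which are encoded within the Hox gene clusters, together took 43.8% ± 2.75 of the signal in B8 (n = 3) and 65.2% ± 2.65 in D3 (n = 2), against 0.628% ± 0.0438 and 0.113% ± 0.0412 at day 0. In B8 they were followed by miR-182-5p (4.44% ± 0.441), miR-292a-5p (3.77% ± 0.684) and miR-181a-5p (3.44% ± 1.22), and in D3 by miR-127-3p (2.82% ± 0.308), miR-181a-5p (2.17% ± 0.0374) and miR-92b-3p (1.95% ± 0.0101). At day 21 in D3 the leading miRNAs were miR-22-3p (9.68% ± 0.50), miR-127-3p (7.93% ± 1.02), miR-10b-5p (7.37% ± 0.645), miR-10a-5p (5.80% ± 0.737) and let-7a-5p (4.11% ± 0.296; n = 3).

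The summed miRNA signal of the deposited values differed between groups. It averaged 140157.7 ± 18026.8 in B8 and 59866.0 ± 11700.5 in D3 at day 0, 174244.8 ± 27062.2 in B8 and 776062.9 ± 76846.4 in D3 at day 7, and 227803.3 ± 50952.2 in D3 at day 21 (SD, n = 3, and n = 2 for D3 at day 7). Fold changes on the deposited scale therefore include a shift common to most miRNAs, with a median log2 change of −0.21 in B8 and 2.25 in D3 from day 0 to day 7, 1.69 in D3 from day 0 to day 21 and −0.60 from day 7 to day 21. The median difference of D3 from B8 was −0.90 at day 0 and 1.71 at day 7. Each comparison is therefore given as deposited and, for its total counts and some named miRNAs, also relative to the median miRNA. Relative changes come from values divided by median-of-ratios factors. Folds of named miRNAs printed without a relative value include the common shift. On that relative scale the medians were −0.06, 0.27, 0.43, 0.02, −0.13 and 0.39 in the same order. Unless called relative, values, folds and log2 changes are on the deposited scale.

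**Figure D1:**
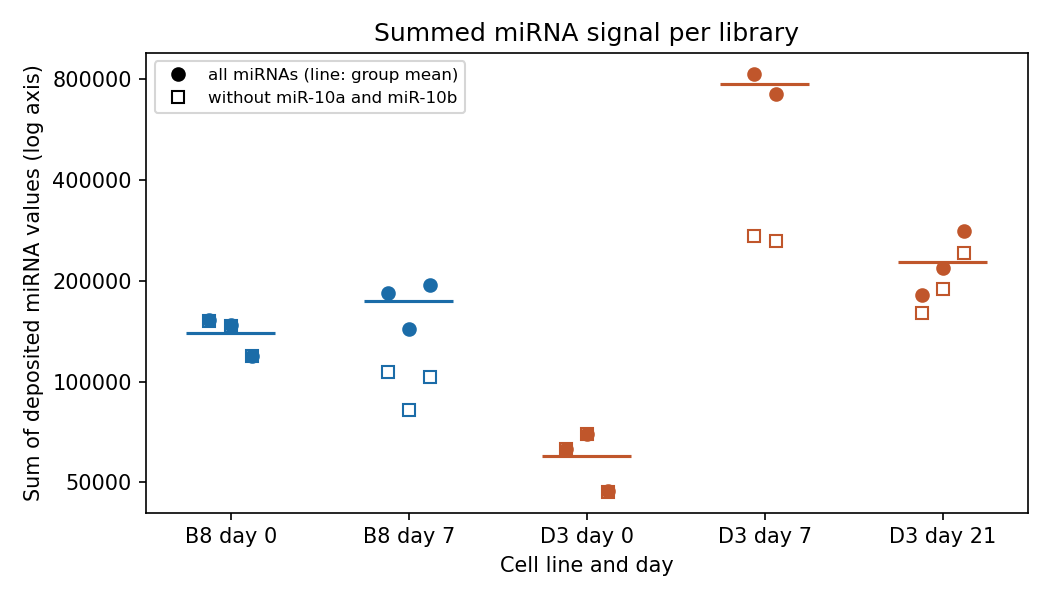
Sum of the deposited miRNA values in each of the 14 libraries (vertical log axis, deposited units) by cell line and day. Filled circles are all miRNAs with the group mean as a line, open squares leave out miR-10a and miR-10b; both D3 day 7 libraries lie above all others, at 830401.5 and 721724.3 with all miRNAs, and remain above the others without miR-10a and miR-10b.

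The change from ESCs to 7-day embryoid bodies was first examined in B8. miRNAs of the Hox clusters and neural miRNAs were among those with the largest rises. miR-10a-5p, whose precursor lies on chromosome 11 (GRCm38, 96317165–96317274) between Hoxb5 and Hoxb4, rose 88.6-fold, from 500.1 ± 85.1 to 44280 ± 6220 (SD, n = 3 each; log2 change 6.47 ± 0.26 SE, limma adjusted p = 2.4e-16). miR-10b-5p, from an intron of Hoxd3 and Hoxd4 on chromosome 2 (74726070–74726137), rose 83.9-fold. miR-615-3p, from an intron of Hoxc5 on chromosome 15 (103014910–103015001), rose from 2.76 ± 1.65 to 212.9 ± 72.5. Of the 8 Hox-embedded miRNAs measured, 7 rose and none fell on either scale. miR-219a-2-3p, a brain-enriched miRNA encoded between Urm1 and Cercam on chromosome 2 (29845631–29845727), went from 0.669 ± 0.17, below the value of 3 reads, to 345 ± 74.4. miR-9-5p, which is expressed in neural progenitors, rose 50.3-fold to 1646 ± 313. In the neural list 10 of 20 members rose and none fell, again on both scales, while miR-128-3p stood at 73.4 ± 24.7 against 94.6 ± 4.52 (adjusted p = 0.21). The miR-99, miR-100 and miR-125 families rose in 6 of 9 members (7 on the relative scale), among them miR-125a-5p (3.25-fold, log2 1.65 ± 0.25, limma adjusted p = 4.3e-06). As deposited, miR-99b-5p at 1.44-fold (limma adjusted p = 0.11) and miR-125b-5p at 1.22-fold (limma adjusted p = 0.41) were not past the threshold.

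miRNAs of pluripotent and proliferating cells were lower in B8 embryoid bodies. In the miR-290 cluster (chromosome 7, 3218626–3220841), 11 of 13 members fell, 10 on the relative scale and 6 with totals equal outside miR-10a and miR-10b. Within it miR-295-3p fell from 15610 ± 3570 to 3127 ± 1620 (log2 −2.45 ± 0.32, adjusted p = 6.8e-07), miR-293-3p from 4200 ± 133.3 to 1017 ± 215.9, and miR-292a-5p from 11100 ± 2360 to 6468 ± 757 (log2 −0.76 ± 0.24, adjusted p = 0.011). The miR-302 cluster, active in pluripotent and epiblast cells and lying in an intron of Larp7 on the opposite strand (chromosome 3, 127545228–127545807), fell in 6 of 7 members on both scales. Its member miR-302d-3p went from 145.8 ± 20.7 to 18.5 ± 5.38. Of 25 miRNAs of the miR-17-92 cluster and its paralogs 18 fell, with miR-18b-5p at 13.97 ± 5.67 against 237 ± 21.7 and miR-92a-3p at 1067 ± 243 against 3038 ± 95.7. miR-25-3p and miR-93-5p were not past the threshold as deposited (limma adjusted p = 0.63 and 0.18). On the relative scale 17 members of this list fell and 1 rose. With totals equal outside miR-10a and miR-10b 14 fell and 1 rose. All 6 miRNAs of the miR-183 cluster (chromosome 6, 30165918–30169737) fell, 5 of them on the relative scale, miR-182-5p from 22380 ± 2860 to 7706 ± 1260. In the Dlk1-Dio3 region 44 of 76 members fell and 2 rose (39 and 2 on the relative scale). Among those that fell was miR-136-5p, from an exon of Rtl1 on the opposite strand (chromosome 12, 109595327–109595388), at 1.64 ± 1.68, below 3 reads, against 51.6 ± 8.14. miR-142a-5p, best known from blood cells, fell from 353.4 ± 67.0 to 20.1 ± 3.02, and miR-29a-3p from 118 ± 12.1 to 9.50 ± 1.10. For the 10 miRNAs named for the largest changes, selected for this, the samples of the days did not overlap, a separation that chance gives to 10% of miRNAs with 3 samples against 3.

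In B8, 260 of 521 miRNAs differed between day 7 and day 0, 114 of them higher and the rest lower. On the relative scale 274 differed, of which 140 were higher. With equal column totals the split was 95 to 186, and with totals equal outside miR-10a and miR-10b it was 159 to 107. By camera with a preset correlation 8 of 17 lists moved together: Hox-embedded (adjusted p = 6.04e-07), neural (0.00055) and miR-99 and miR-125 (0.00125) upward, and Dlk1-Dio3 (4.65e-07), miR-17-92 (3.25e-05), miR-290 cluster (0.00195), miR-302 cluster (0.00344) and miR-183 cluster (0.00767) downward. With an estimated correlation no list kept its call: the adjusted p for those lists was 0.101, 0.112, 0.14, 0.155, 0.229, 0.457, 0.155 and 0.14 in that order. The let-7 family went both ways. In it 7 of 15 members rose and 2 fell, with let-7a-5p 2.53-fold higher (log2 1.33 ± 0.23 SE) and let-7i-5p at 328.1 ± 52.9 against 646.5 ± 91.0 (list adjusted p = 0.10). The remaining lists were not past the threshold. Of mesenchyme and smooth muscle miRNAs 1 of 13 rose and 5 fell, of epithelial ones 1 of 11 and 4, of endodermal ones 3 of 11 and 1, of blood and endothelial ones 1 of 11 and 4, and of the miR-34 and miR-449 family 0 of 5 and 3. Of muscle miRNAs 1 of 4 rose and 0 fell. Among them miR-1a-3p was at 1.74 ± 0.982 against 0.195 ± 0.338, both below 3 reads, and miR-208b-3p was near 0 on both days. Of the Sfmbt2 cluster 4 of 42 rose and 0 fell (8 and 0 on the relative scale, 3 and 4 with equal column totals). Of entries resembling rRNA or tRNA fragments, a sign of RNA quality, 1 of 4 rose and 0 fell (3 and 0 on the relative scale). Falls under equal column totals reached 7 epithelial and 7 blood and endothelial miRNAs, and 2 endodermal miRNAs rose while 2 fell. Totals equal outside miR-10a and miR-10b gave 3 blood and endothelial miRNAs up and 3 down, 12 and 0 of the Sfmbt2 cluster and 7 and 0 of the let-7 family.

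The same interval was examined in D3, where the day 7 bodies had far higher levels of the Hox miRNAs than the ESCs. miR-10a-5p went from 35.01 ± 8.77 (n = 3) to 322100 ± 44200 (n = 2), a 9200-fold rise (log2 13.2 ± 0.29, adjusted p = 3.6e-22; relative log2 change 10.9), and miR-10b-5p rose 6140-fold to 184700 ± 26400. miR-10a-3p was at 0 in all 3 day 0 libraries and reached 923 ± 171, at least 489-fold higher than a floor of 3 reads per library. Of the 8 Hox-embedded miRNAs 7 rose on both scales and 1 fell on the relative scale. Neural miRNAs rose in 20 of 20 cases as deposited and in 14 relative to the median, while with equal column totals 9 rose and 3 fell. Neural miRNAs that rose on both scales included miR-9-5p, 801-fold higher (11.3 ± 5.597 to 9032 ± 1200, relative log2 7.46), and miR-219a-2-3p, going from 1.09 ± 0.574, below 3 reads, to 1365 ± 157. The let-7 family, which accumulates as cells leave the pluripotent state, rose in 14 of 15 members on both scales. let-7a-5p was 104-fold higher (6194 ± 49.8 against 59.8 ± 6.73) and let-7i-5p 93.9-fold. All 9 members of the miR-99, miR-100 and miR-125 families rose on both scales, miR-125b-5p by 268-fold. In the mesenchyme and smooth muscle list 12 of 13 rose, 9 on the relative scale where 1 fell, and 8 with equal column totals where 3 fell. miR-199a-3p was 519-fold higher (2713 ± 390 against 5.23 ± 1.53), and miR-143-3p 25.2-fold. miR-181a-5p rose 1460-fold, from 11.5 ± 1.75 to 16800 ± 1370.

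miR-290 cluster miRNAs fell in D3 as well, in 11 of 13 members and in 12 on the relative scale: miR-293-3p went from 1606 ± 233 to 410 ± 25.6 (log2 −1.96 ± 0.25, adjusted p = 1.4e-07), miR-292a-5p from 3544 ± 1050 to 1480 ± 127.1, and miR-295-3p from 5583 ± 1540 to 2164 ± 378.9. In the rodent-specific Sfmbt2 intron cluster (71 annotated precursors of the list inside Sfmbt2 on chromosome 2, 10370510–10595253, and 10 on 7 other chromosomes; counts are for the whole list), 12 of 42 members fell as deposited, 35 on the relative scale, and none rose on either. miR-467c-5p fell from 148 ± 17.3 to 38.7 ± 4.94, and miR-669a-5p to 87.0 ± 17.7 (log2 −1.23 ± 0.28 SE). For the following groups the counts depended on the scale. miR-302 cluster had 1 member up (miR-302b-3p) and 1 down of 7 as deposited, and 6 down on the relative scale, with miR-302d-3p at 91.1 ± 5.84 against 58.7 ± 15.0 (relative log2 −1.63, adjusted p = 5.4e-06). miR-182-5p was at 5495 ± 687 against 8338 ± 2200 (adjusted p = 0.067), and its cluster had 1 of 6 members down as deposited and 6 on the relative scale. In the Dlk1-Dio3 region 57 of 76 rose and 1 fell as deposited, whereas relative to the median 4 rose and 25 fell, and with equal column totals 52 fell. miR-127-3p (2.71-fold higher; relative log2 −0.85, adjusted p = 9.1e-05) and miR-541-5p (2.84-fold higher; relative log2 −0.77) were among those that turned. Muscle miRNAs stayed at low levels though 4 of 4 rose (2 on the relative scale), with miR-1a-3p at 6.32 ± 1.18 against 0 in all day 0 libraries, at least 3.34-fold above the floor.

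In D3, 403 of 521 miRNAs differed between day 7 and day 0, 36 of them lower and the rest higher. Relative to the median, 328 differed, 188 higher and 140 lower, of which 224 were called in the direction of the deposited scale and 34 in the opposite one. With equal column totals the split was 110 higher to 233 lower, and with totals equal outside miR-10a and miR-10b 193 to 131. Camera called 9 lists: upward miR-99 and miR-125 (adjusted p = 0.00018), let-7 (0.000261), Hox-embedded (0.00149), mesenchyme (0.00944) and neural (0.0115). Downward were Sfmbt2 (2.47e-19), miR-290 cluster (3.14e-12), miR-183 cluster (0.00158) and miR-302 cluster (0.0101), whose median change as deposited was 0.17, opposite in sign to the test and to its mean of −0.34. With an estimated correlation the Sfmbt2 list kept its call (adjusted p = 0.0266) and the others lost theirs. These had adjusted p = 0.0823, 0.194, 0.156, 0.444 and 0.157 for the upward lists and 0.0823, 0.0823 and 0.183 for the remaining downward lists, in the order given. Of lists not past the threshold, 9 of 11 endodermal, 6 of 11 blood and endothelial, 6 of 11 epithelial, 13 of 25 miR-17-92, 4 of 5 miR-34 and miR-449 and 1 of 4 fragment-like miRNAs rose as deposited, against 6, 5, 1, 3, 3 and 1 on the relative scale. As deposited 3 blood and endothelial members and 1 epithelial member fell, while on the relative scale 4 and 6 of these fell, as did 10 miR-17-92, 2 miR-34 and miR-449 and 1 fragment-like member, so the epithelial and miR-17-92 lists turned with the scale. Equal column totals gave 5 endodermal miRNAs up and 2 down, 4 and 4 blood and endothelial, 0 and 10 epithelial, 0 and 20 miR-17-92, 2 and 2 miR-34 and miR-449, 0 and 3 fragment-like and 1 and 0 muscle miRNAs. The muscle and Dlk1-Dio3 lists were not past the threshold either (adjusted p = 0.899 and 0.553).

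The longer interval, from ESCs to outgrowths at day 21, was followed in D3. Muscle, mesenchymal and let-7 miRNAs were higher in the outgrowths. miR-208b-3p, encoded in an intron of the heart myosin gene Myh7 (chromosome 14, 54975700–54975776), reached 242.4 ± 123.7 from 0.345 ± 0.598, below 3 reads (n = 3 each, limma adjusted p = 3.9e-11). miR-1a-3p, a miRNA of heart and skeletal muscle, reached 115.1 ± 79.1 from 0 in all day 0 libraries, at least 60.9-fold above the floor. All 4 muscle miRNAs measured rose on both scales. All 13 mesenchyme and smooth muscle miRNAs rose, 11 of them on the relative scale, with miR-199a-3p 733-fold higher (3831 ± 1380 against 5.23 ± 1.53, relative log2 7.88) and miR-143-3p (chromosome 18, 61649196–61649258) 56.5-fold higher at 6308 ± 2070. The let-7 family rose in 15 of 15 members on both scales, let-7i-5p by 313-fold to 6380 ± 2170 and let-7a-5p by 158-fold to 9470 ± 2780. miR-99 and miR-125 miRNAs rose in 9 of 9 (8 on the relative scale), with miR-125b-5p 179-fold higher. miR-99a-5p went from 0.18 ± 0.311, below 3 reads, to 276.9 ± 84.7. Hox-embedded miRNAs were still above day 0 in 8 of 8 cases (7 on the relative scale), miR-10b-5p by 565-fold, and miR-10a-5p at 13400 ± 4240. Neural miRNAs rose in 18 of 20, and on the relative scale in 13 with 1 lower. miR-9-5p was 115-fold higher. miR-181a-5p rose 702-fold.

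Among pluripotency miRNAs in these outgrowths, the miR-290 cluster fell in 12 of 13 members on both scales, miR-293-3p 10-fold, from 1606 ± 233 to 160 ± 32.0 (log2 −3.33 ± 0.22, adjusted p = 1.3e-12), miR-295-3p from 5583 ± 1540 to 824.1 ± 176, and miR-290a-3p from 33.5 ± 12.4 to 2.68 ± 1.09. Of 7 miR-302 members 4 rose and none fell as deposited, 3 rose and 1 fell on the relative scale, and 2 rose and 2 fell with equal column totals, and the list was not past the threshold (camera adjusted p = 0.85). miR-302d-3p was at 338 ± 98.9 against 58.7 ± 15.0 (relative log2 0.95, adjusted p = 4e-04) and miR-302a-3p at 124.4 ± 31.4 against 26.3 ± 8.37. Of miRNAs above the median level the largest fall was that of miR-6539, from an intron of Dock5 (chromosome 14, 67859636–67859745), from 74.4 ± 15.9 to 2.45 ± 0.506. Sfmbt2 cluster miRNAs fell in 18 of 42 members (34 on the relative scale) and rose in none, with miR-467c-5p at 32.4 ± 8.97 against 148 ± 17.3. In the miR-17-92 group 7 of 25 rose and 9 fell as deposited, and 16 fell with none rising on the relative scale: miR-92a-3p fell from 1227 ± 167 to 635.0 ± 40.9, while miR-25-3p (2.72-fold higher) and miR-93-5p (2.22-fold higher) had relative log2 changes of −0.14 and −0.42. Dlk1-Dio3 miRNAs likewise turned with the scale, from 43 up and 4 down of 76 to 5 up and 27 down. In the miR-183 cluster 2 of 6 fell as deposited and 6 on the relative scale.

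In D3, 393 of 521 miRNAs differed between day 21 and day 0, 340 higher and 53 lower, and relative to the median 328 differed, 198 higher and 130 lower. The split was 177 to 158 with equal column totals and with totals equal outside miR-10a and miR-10b 190 of 331 were higher. Camera called 8 lists: let-7 (adjusted p = 7.99e-06), mesenchyme (3e-04), miR-99 and miR-125 (0.000693) and Hox-embedded (0.0097) upward. Downward were the miR-290 cluster (5.86e-15), Sfmbt2 (3.88e-15), miR-17-92 (0.000177, with a median of 0.06 and a mean of −0.18 as deposited) and miR-183 cluster (0.00118). None kept its call with an estimated correlation (adjusted p = 0.164, 0.238, 0.107, 0.238, 0.082, 0.0612, 0.238 and 0.082 in that order). The muscle list was not past the threshold (adjusted p = 0.10), nor were the neural, miR-302 cluster, Dlk1-Dio3 (2 up and 33 down with equal column totals), endodermal (10 of 11 rose, 9 on the relative scale), blood and endothelial (8 rose and 2 fell of 11, and 6 and 4 with equal column totals), epithelial (8 of 11 rose, but 2 rose and 3 fell on the relative scale and 2 and 5 with equal column totals), miR-34 and miR-449 (5 of 5 rose, 3 on the relative scale) and fragment-like (2 of 4 rose, but 1 fell on the relative scale and 4 with equal column totals) lists.

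Within D3 differentiation, outgrowths at day 21 were then set against embryoid bodies at day 7. Hox miRNAs were lower at day 21 than at day 7. miR-10a-5p fell 24-fold, from 322100 ± 44200 (n = 2) to 13400 ± 4240 (n = 3; log2 −4.63 ± 0.29, adjusted p = 1.2e-11), miR-10b-5p fell 10.9-fold, and miR-615-3p went from 1128 ± 78.2 to 22.1 ± 2.21. Of 8 Hox-embedded miRNAs 6 fell on both scales, and 1 rose on the relative scale and 2 with equal column totals. Neural miRNAs fell in 12 of 20 members (6 on the relative scale, where 1 rose; 2 with equal column totals, where 1 rose and the median was 0.22), miR-9-5p from 9032 ± 1200 to 1297 ± 354 and miR-219a-2-3p from 1365 ± 157 to 248 ± 23.6. Muscle miRNAs rose in 4 of 4 members, 3 on the relative scale, with miR-208b-3p 65.9-fold, miR-1a-3p 18.2-fold and miR-133a-3p 14.7-fold higher. The miR-302 cluster rose in 5 of 7 on both scales (miR-302d-3p 3.71-fold and miR-302a-3p 3.69-fold), and 8 of 15 let-7 miRNAs rose and 2 fell (10 and 1 on the relative scale), among them let-7f-5p (4.76-fold), let-7d-5p (4.37-fold) and let-7b-5p (4.24-fold). miR-142a-5p rose from 2.28 ± 1.20 to 21.3 ± 2.07. Of the mesenchyme list 3 of 13 rose and 1 fell as deposited and 8 rose on the relative scale, miR-143-3p by 2.24-fold, while miR-199a-3p was at 3831 ± 1380 against 2713 ± 390 (adjusted p = 0.34).

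Between days 7 and 21 of D3, 42 of 521 miRNAs were higher and 164 lower at day 21. Relative to the median 84 were higher and 54 lower. The split was 198 to 11 with equal column totals and 53 to 81 with totals equal outside miR-10a and miR-10b. Without replicate 2 of D3 day 7, which leaves 1 library at that day, 116 miRNAs differed in all. Camera called 10 lists: upward miR-302 cluster, let-7 and muscle (each adjusted p = 6.22e-05), mesenchyme (0.00308) and epithelial (0.00923; 1 of 11 rose, 6 on the relative scale). Downward were Hox-embedded and miR-17-92 (each 6.22e-05; 19 of 25 miR-17-92 miRNAs fell, 10 on the relative scale), miR-99 and miR-125 (0.00499; 8 of 9 fell, 3 on the relative scale), neural (0.0179) and miR-290 cluster (0.0283; 10 of 13 fell, 2 on the relative scale). With an estimated correlation the muscle list kept its call (adjusted p = 0.034), and the others lost theirs. These had adjusted p = 0.105, 0.207, 0.346 and 0.346 for the remaining upward lists and 0.112, 0.238, 0.207, 0.207 and 0.495 for the downward lists in the order given. With equal column totals the falls of the miR-290 cluster, miR-17-92 and miR-99 and miR-125 lists turned, to 3, 1 and 2 members higher and none lower, while of the neural list 1 member was higher and 2 lower. The same setting had 11 mesenchyme, 9 epithelial, 12 let-7 and 5 endodermal miRNAs higher and none lower. It also had 3 miR-34 and miR-449, 3 miR-183 cluster and 3 blood and endothelial miRNAs higher and none lower, and 1 fragment-like miRNA higher. On the relative scale the blood and endothelial list likewise had 3 miRNAs higher and 0 lower. Totals equal outside miR-10a and miR-10b gave 2 mesenchyme miRNAs higher and none lower, 0 and 6 of the Dlk1-Dio3 region and 0 and 0 of the Sfmbt2 cluster. Not past the threshold were the Dlk1-Dio3 (1 of 76 rose and 23 fell; 5 and 3 on the relative scale, 34 and 0 with equal column totals), Sfmbt2 (2 of 42 fell as deposited, 3 rose on the relative scale and 16 with equal column totals), endodermal (2 of 11 rose and 4 fell, 3 and 0 on the relative scale), blood and endothelial (3 of 11 rose and 3 fell), miR-34 and miR-449 (1 of 5 rose), miR-183 cluster (0 of 6 changed) and fragment-like (1 of 4 fell) lists.

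**Figure D2:**
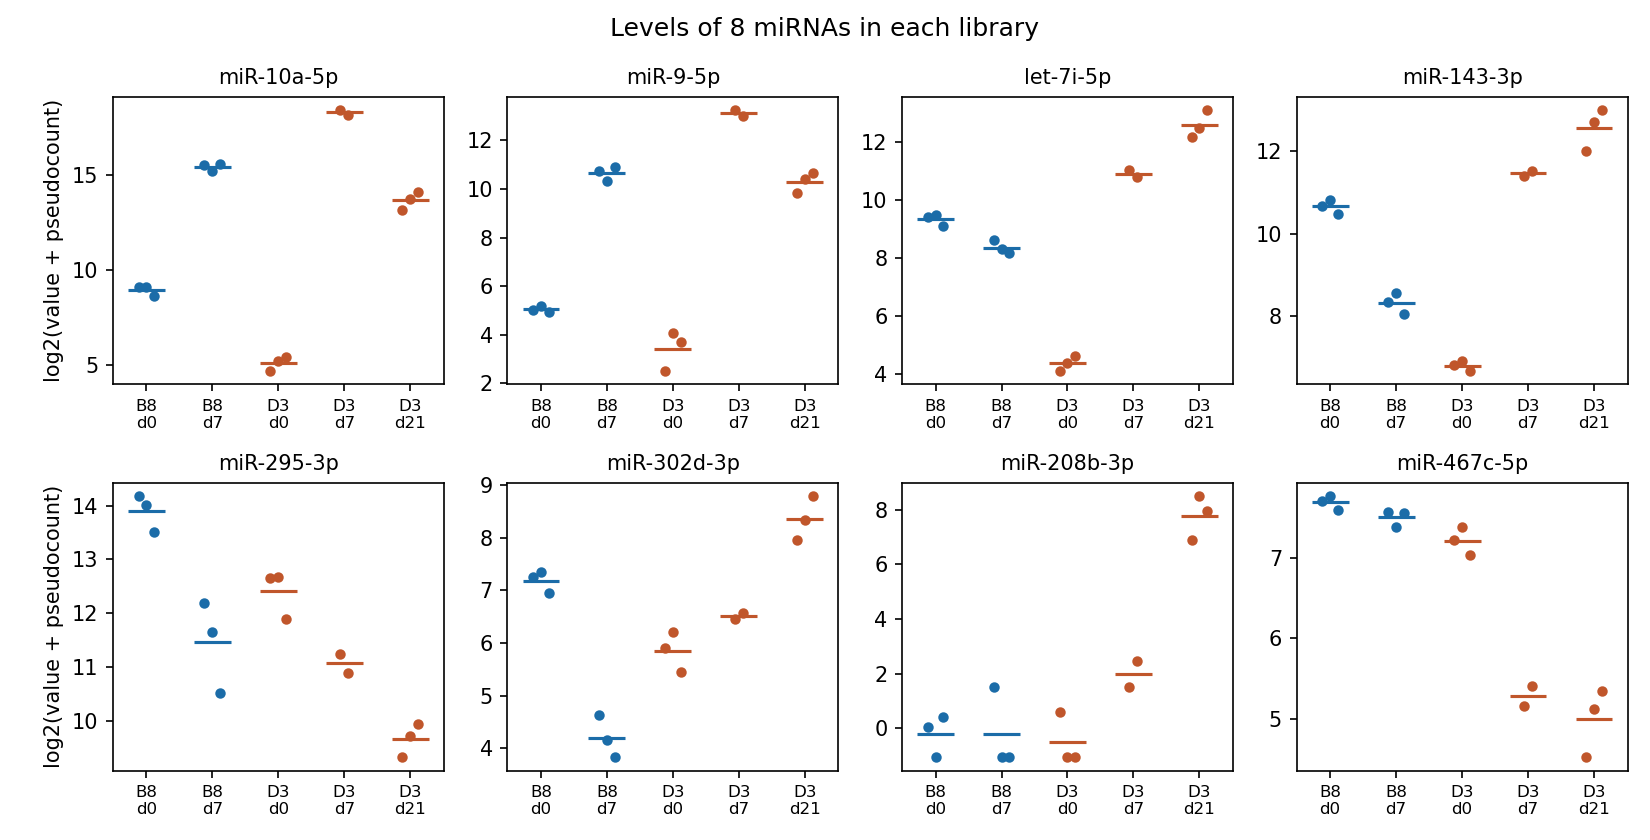
Levels of 8 miRNAs in each library, as log2 of the deposited value plus the pseudocount (vertical axes, each with its own range), for B8 (blue) and D3 (orange) by day; points are libraries and lines are group means. miR-10a-5p and miR-9-5p peak in D3 at day 7, miR-208b-3p is high at D3 day 21, and let-7i-5p and miR-143-3p are lower in D3 than in B8 at day 0.

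The undifferentiated lines were compared with each other. miRNAs of mesenchymal cells and of the let-7 family were lower in D3 than in B8 ESCs. miR-199a-3p was at 338 ± 5.81 in B8 and 5.23 ± 1.53 in D3, a 64.7-fold difference (n = 3 each; log2 −5.93 ± 0.31 for D3 minus B8, adjusted p = 7.4e-14; relative −4.96). miR-214-3p, which shares its host transcript Dnm3os with miR-199a-2 on chromosome 1 (162223368–162223477), was at 23.0 ± 0.291 in B8 and 0 in every D3 library, at least 12.2-fold lower. miR-143-3p was 14.5-fold lower in D3 at 112 ± 9.60 against 1621 ± 187. In the mesenchyme and smooth muscle list 11 of 13 members were lower in D3, 9 on the relative scale, and none was higher. let-7 miRNAs were lower in D3 in 12 of 15 cases (11 relative), with let-7i-5p at 20.4 ± 3.80 against 646.5 ± 91.0 and let-7a-5p at 59.8 ± 6.73 against 926.5 ± 59.96. miR-99 and miR-125 miRNAs were lower in 9 of 9 cases (6 relative), miR-125b-5p by 34.6-fold, and 5 of 8 Hox-embedded miRNAs were lower (4 relative), miR-10a-5p by 14.3-fold and miR-10b-5p by 12.8-fold.

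In the ESC clusters, all 13 miRNAs of the miR-290 cluster were lower in D3 as deposited, miR-295-3p at 5583 ± 1540 against 15610 ± 3570, but 4 on the relative scale and 1 with equal column totals, and 3 of 7 miR-302 miRNAs were lower as deposited and none relative to the median. Of 11 epithelial miRNAs 8 were lower in D3 (5 relative), miR-205-5p by 4.77-fold and miR-141-3p by 4.90-fold. The Dlk1-Dio3 miRNAs had 1 member higher and 3 lower of 76 as deposited, whereas 26 were higher and none lower in D3 relative to the median. miR-127-3p was at 8039 ± 1470 against 9485 ± 893 (relative log2 0.80, adjusted p = 0.00016). miR-2137, from an intron of Zfp185 on chromosome X (72992079–72992144), was higher in D3 at 197 ± 55.7 against 33.4 ± 16.6, and miR-410-5p at 60.2 ± 10.5 against 20.3 ± 4.78. Entries that resemble rRNA or tRNA fragments were partly higher in D3 (2 of 4, with 1 lower), miR-6240 at 53.2 ± 20.8 against 26.9 ± 9.04.

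At day 0, 245 of 521 miRNAs differed between the lines, 5 higher and 240 lower in D3. Relative to the median 40 were higher and 82 lower. Under equal column totals 113 differed (48 to 65), and with totals equal outside miR-10a and miR-10b 116 (50 to 66). Camera called 11 lists. Those lower in D3 were let-7 (adjusted p = 2.08e-06), mesenchyme (2.1e-06), miR-99 and miR-125 (9.73e-05), miR-290 cluster and miR-17-92 (each 0.00489), Hox-embedded (0.02) and epithelial (0.0416), and those higher were Dlk1-Dio3 (3.95e-08), fragment-like (0.0191), neural (0.0238) and endodermal (0.0396). Of 25 miR-17-92 miRNAs 22 were lower in D3 (5 relative, 1 with equal column totals). The median as deposited was below 0, opposite to the test, for the Dlk1-Dio3 (−0.25), neural (−0.35; 3 of 20 lower as deposited, 1 higher relative, 2 higher with equal column totals) and endodermal (−0.38; 2 of 11 lower as deposited, none relative) lists. None kept its call with an estimated correlation, with adjusted p = 0.151, 0.151, 0.151, 0.357, 0.357, 0.26 and 0.357 for the lower lists and 0.151, 0.151, 0.186 and 0.151 for the higher lists in the order given. The blood and endothelial list was not past the threshold (5 of 11 lower; 3 lower and 1 higher relative to the median), nor were the miR-34 and miR-449 (4 of 5 lower), Sfmbt2 (14 of 42 lower, none relative to the median, where 2 were higher), miR-183 cluster (4 of 6 lower, 1 relative, 0 with equal column totals), miR-302 cluster and muscle (0 of 4) lists.

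At day 7 the embryoid bodies of the lines differed in several groups. Dlk1-Dio3 miRNAs were higher in D3 in 70 of 76 cases, 44 relative to the median, and lower in none on either scale, with 24 higher and 1 lower under equal column totals. miR-127-3p was at 21760 ± 224 (n = 2) against 3329 ± 456 in B8 (n = 3, log2 2.72 ± 0.25, limma adjusted p = 3.1e-09, relative 1.24). miR-136-5p was at 68.6 ± 3.84 in D3 against 1.64 ± 1.68 in B8, the latter below 3 reads. miR-126a-5p and miR-126a-3p, endothelial miRNAs from Egfl7 on chromosome 2 (26591357–26591429), were 29.6-fold and 20.5-fold higher in D3. Mesenchyme miRNAs were higher in 13 of 13 cases (7 relative, 1 with equal column totals), miR-143-3p by 8.67-fold and miR-199a-3p by 5.93-fold. In the other direction the miR-290 cluster was lower in D3 in 11 of 13 cases (13 relative), miR-292a-5p at 1480 ± 127.1 against 6468 ± 757 and miR-293-3p at 410 ± 25.6 against 1017 ± 215.9. The Sfmbt2 cluster was lower in 28 of 42 cases (33 relative) and higher in none, with miR-467c-5p at 38.7 ± 4.94 against 181 ± 12.6 and miR-669a-5p at 87.0 ± 17.7 against 369.5 ± 34.99. miR-142a-5p was also lower, at 2.28 ± 1.20 against 20.1 ± 3.02. Epithelial miRNAs were near equal as deposited (1 higher and 1 lower of 11; miR-205-5p 453.7 ± 69.0 against 389.8 ± 58.0) and lower in D3 relative to the median in 8 of 11. let-7 miRNAs were higher in 14 of 15 cases as deposited and in 3 relative to the median, but 4 were lower and none higher with equal column totals. let-7a-5p was 2.64-fold higher with a relative log2 difference of −0.06, and let-7i-5p 5.84-fold with 1.08. miR-302 miRNAs were higher in 4 of 7 (3 relative, 1 with equal column totals), and neural ones in 18 of 20 (7 relative, 1 with equal column totals), miR-9-5p by 5.49-fold.

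At day 7, 392 of 521 miRNAs differed between the lines, 344 higher and 48 lower in D3. Relative to the median 40.7% of the 521 differed, with 85 lower and the rest higher. With equal column totals 163 differed, 41 of them higher, and with totals equal outside miR-10a and miR-10b 202 (120 to 82). Camera called 5 lists: Dlk1-Dio3 (adjusted p = 5.77e-07) and mesenchyme (0.0284) higher, and Sfmbt2 (2.54e-36), miR-290 cluster (4.92e-14) and epithelial (0.0176, with a median of 0.02 as deposited) lower. With an estimated correlation the Sfmbt2 list kept its call (adjusted p = 0.00214) and the others lost theirs (adjusted p = 0.362, 0.567, 0.114 and 0.399 in that order). Of lists not past the threshold, 9 of 9 miR-99 and miR-125 (4 relative, 0 with equal column totals), 6 of 8 Hox-embedded (4 relative, with 2 lower on both scales; 1 higher and 2 lower with equal column totals), 18 of 25 miR-17-92 (2 relative, with 6 lower; 0 with equal column totals, with 8 lower), 8 of 11 endodermal (6 relative, with 1 lower; 5 with equal column totals, with 1 lower), 5 of 11 blood and endothelial (4 relative, with 3 lower on both scales; 2 with equal column totals, with 4 lower), 3 of 4 muscle (none relative), 4 of 5 miR-34 and miR-449 (1 relative, with 1 lower; 0 with equal column totals, with 1 lower), 0 of 6 miR-183 cluster (3 lower relative) and 1 of 4 fragment-like (none relative; 1 lower with equal column totals) miRNAs were higher in D3.

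Whether the lines changed differently from day 0 to day 7 was tested by the interaction of line and day. A difference in change includes any gap between the lines at day 0. The let-7 list had a relative median difference of D3 from B8 of −2.43 at day 0 and 0.32 at day 7. For mesenchyme miRNAs this median was −3.18 at day 0 and 1.22 at day 7. Among the miRNAs with the smallest adjusted p, miR-199a-3p changed by 8.92 on the log2 scale in D3 and 0.30 in B8 (interaction 8.63 ± 0.46 SE, adjusted p = 9e-14; relative 6.18), and let-7i-5p by 6.53 in D3 and −0.98 in B8 (interaction 7.51 ± 0.37, adjusted p = 6.1e-14; adjusted p = 5.4e-09 on the relative scale). In the other direction miR-467c-5p of the Sfmbt2 cluster changed by −1.92 in D3 and −0.19 in B8 (interaction −1.74 ± 0.37, adjusted p = 0.00019; relative −4.25). The change differed for 387 of 521 miRNAs, more positive in D3 for 374 and less for 13; relative to the median it differed for 170, 105 and 65. With equal column totals it differed for 159 (52 to 107) and with totals equal outside miR-10a and miR-10b for 161 (91 to 70). Both lines also shared changes: 107 miRNAs rose in both by day 7, against 80.3 for independent lists (one-sided Fisher's exact p = 8.94e-12), and 20 fell in both, against 10.1 (p = 0.00029), while 86 were called in opposite directions. Relative to the median 115 rose in both (50.5 for independent lists, one-sided Fisher's exact p = 3.38e-40) and 78 fell in both (36.0, p = 7.48e-20 by the same exact test). On that scale 22 went opposite ways. Fisher's test takes miRNAs as independent, which members of a cluster are not, so these p-values only describe the overlap. Across miRNAs, which are not independent replicates, the log2 changes of the lines had Pearson's r = 0.678 and Spearman's rho = 0.603.

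**Figure D3:**
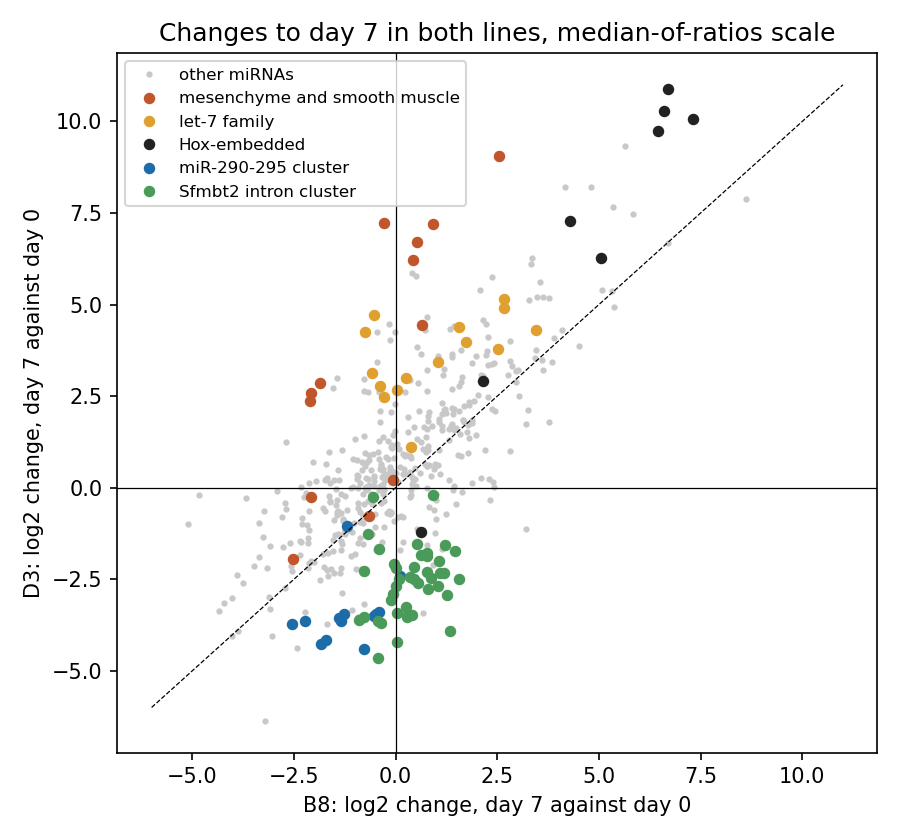
Relative log2 change from day 0 to day 7 in B8 (horizontal axis) and D3 (vertical axis) for 521 miRNAs, on the median-of-ratios scale; coloured points are members of 5 lists and the dashed line marks equal change. Hox-embedded miRNAs rise in both lines apart from 1 member that falls in D3, mesenchyme miRNAs lie mostly above the dashed line, and the 42 Sfmbt2 cluster miRNAs lie below 0 in D3 and between −0.90 and 1.55 in B8, 12 of them below 0.

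Adjusted over the list alone, the deposited counts of rising and falling members were those given above in all but 19 of the 102 list tests, and differed by at most 3 members in those. In B8 from day 0 to day 7, adjusted over the list alone, 7 miR-302 cluster, 19 miR-17-92 and 3 let-7 miRNAs fell and 3 Sfmbt2 miRNAs rose. In D3, 11 Sfmbt2 and 0 epithelial miRNAs fell from day 0 to day 7. By day 21, 8 miR-17-92 and 17 Sfmbt2 miRNAs fell against day 0, and 9 epithelial miRNAs rose and 1 fell. Against day 7, 9 let-7 miRNAs rose and 3 fell, 0 Dlk1-Dio3 miRNAs rose and 22 fell, and 0 Sfmbt2 miRNAs fell. Between the lines at day 0, 6 Hox-embedded, 0 endodermal, 1 Dlk1-Dio3 and 11 Sfmbt2 miRNAs were lower in D3, and at day 7, 3 miR-302 cluster, 71 Dlk1-Dio3 and 5 miR-34 and miR-449 miRNAs were higher.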

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

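The tests of scaling, of miR-10a and miR-10b signal and of mesenchymal cells were chosen only after the results they bear on were seen; the tests of read depth, single libraries, low values and shared reads were set before their results. A difference in change includes any gap between the lines at day 0. The change from day 0 to day 7 differed between D3 and B8, by the interaction test, for 387 miRNAs. It was more positive in D3 for let-7i-5p by 7.51 on the log2 scale, miR-143-3p by 6.98, miR-125b-5p by 7.70, miR-199a-3p by 8.63 and miR-125b-1-3p by 7.84. It was more negative in D3 for miR-467c-5p (−1.74), miR-669h-5p (−3.12), miR-669f-5p (−1.70), miR-669l-5p (−1.37) and miR-669a-5p (−1.28).

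Most miRNAs called in D3 from day 0 to day 7 were higher at day 7. Equal numbers of reads did not remove this pattern: with every library thinned to 56377 reads, 84.4% of 270 calls were higher. The thinned libraries were set back to their deposited totals, which keeps the common shift, so a high share was likely from the start. Depth that entered the values through the scaling was not tested. The scaling of the deposited values stays open: 57.3% of calls were higher with median-of-ratios factors, but these centre the libraries, which evens out the share whatever the cause. The test of miR-10a and miR-10b signal decided nothing either, since the mean column total without them, 4.48 times that of day 0, restates that other miRNAs were higher. A difference in miRNA content between ESCs and embryoid bodies may also contribute and was not tested.

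miRNAs of the let-7 family and of mesenchyme were higher in B8 than in D3 at day 0. For the mesenchyme list scaling was excluded, since its median log2 difference, −3.78 as deposited, was at most −3.04 under the 3 other scalings, and so was a single deviating library, since at least 10 members were called lower in D3 with any library left out, against 11 with all; the let-7 list, with medians of −3.07 and at most −2.26, was not tested for single libraries. Cells of mesenchymal type in the B8 day 0 cultures stay open as a candidate explanation without support from a test: that 77.8% of the 9 abundant list members were called higher in B8 on the relative scale restates the pattern, since these members had already been seen to differ. The labels say that no feeder layer was used. A difference between the lines themselves also stays open, as untested.

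The Sfmbt2 cluster fell from day 0 to day 7 in D3, in 12 of 42 members as deposited and in 37 with equal column totals. In B8 4 members rose and 0 fell as deposited, while 3 rose and 4 fell with equal column totals. A low mean level alone did not give the pattern. None of 10000 random lists matched on mean level over all libraries had a median interaction as low as −0.85 (lowest 1.71). This gives 1e-04, the smallest share that 10000 lists can give. The share does not measure chance: members may move together more than those of random lists, and this list was singled out for its change. Reads counted at several members stay open: the members' summed value also differed in change (log2 −1.08, adjusted p = 0.0045), but shared reads would carry the same change into the sum, so the planned test could not exclude them. A difference between the lines also stays open, as untested, and other technical causes were not tested.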

How the results depend on the processing

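The settings with equal totals outside miR-10a and miR-10b, both edgeR fits, and the overlap under median-of-ratios factors and the replicate block were chosen only after the results were seen. With a filter at 50 per 1000000, under which fewer miRNAs were tested, 251 miRNAs differed in D3 at day 7 against day 0, 258 at day 21 against day 0 and 261 between the lines at day 7. Leaving out each replicate in turn gave 116 to 185 miRNAs for D3 day 21 against day 7, the lowest without D3 day 7 replicate 2, where the lone sample is assumed to vary like the other groups; no other number of differing miRNAs moved by over 1.5 times when a library was left out, though those higher in D3 than in B8 at day 0 went from 5 to 3 without B8 day 0 replicate 3. The next counts are for equal column totals, median-of-ratios factors, edgeR with TMM factors and equal totals outside miR-10a and miR-10b, in that order, and 3 of them are rounded. Between the lines 113, 1.2e+02 (40 higher and 82 lower), 119 and 116 miRNAs differed at day 0, and 163, 2.1e+02 (85 lower), 2.2e+02 (103 higher and 113 lower) and 202 at day 7. In the interaction 159, 170, 159 and 161 differed. For D3 day 21 against day 7 the last of these settings gave 1.3e+02 (rounded; 53 higher and 81 lower). With an estimated correlation 0, 1, 0, 1, 0 and 1 lists moved together in the order of the report, against 8, 9, 8, 10, 11 and 5. For D3 against B8 at day 0, 7 lists did with equal column totals and 7 with equal totals outside miR-10a and miR-10b. The overlap between the lines, 107 higher and 20 lower in both, became 221 with equal column totals, 193 with median-of-ratios factors and 191 with equal totals outside miR-10a and miR-10b. Other alternatives left these counts within 1.5 times, among them the replicate block, with 264, 404, 400, 202, 244 and 387 miRNAs in the 6 comparisons of groups. Residuals of samples with the same replicate number, within or across lines, had correlations between −0.13 and 0.14, with 2 of 26 pairs over 0.1. With 2 or 3 samples per group, this cannot exclude that replicate numbers pair the samples. Of the values of named miRNAs under the alternatives 3780 kept their side of the threshold and, where called, their direction. Of the others 85 came past it, 91 changed sign where called with either setting and the rest were no longer past it. Of list results 418 kept their side of the threshold and, where called, their direction, while 65 lost and 27 gained the call. Where called with either setting, 0 changed the direction given by camera, though member counts of some lists turned as the report gives. Changes of sign are counted here and below only where called with either setting. Each of them came with another scaling, which multiplies each library by its own factor. For the other changes the cause was not tested. The settings for comparisons with B8 at day 21 were not run. Depth limits the low values: 3 reads stand for 0.885 to 4.12 units in single libraries, and for 1.02 to 2.72 as group means.

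With median-of-ratios factors the log2 values that changed sign were, for D3 day 7 against day 0, miR-302b-3p (−0.63), miR-541-5p (−0.77), miR-127-3p (−0.85), miR-302d-3p (−1.63), miR-302a-3p (−1.89). They were for D3 day 21 against day 0, miR-25-3p (−0.14), miR-127-3p (−0.42), miR-93-5p (−0.42), miR-541-5p (−0.70); for D3 day 21 against day 7, miR-127-3p (0.43), miR-541-5p (0.0725); for D3 against B8 at day 0, miR-541-5p (0.85), miR-127-3p (0.80), miR-410-3p (0.78), miR-375-3p (0.36), miR-192-5p (0.26); for D3 against B8 at day 7, let-7a-5p (−0.0642), miR-205-5p (−1.25), miR-141-3p (−1.43). With equal column totals the log2 values that changed sign were, for D3 day 7 against day 0, miR-128-3p (−0.64), miR-302b-3p (−2.01), miR-541-5p (−2.19), miR-127-3p (−2.26), miR-302d-3p (−3.03), miR-302a-3p (−3.27). They were for D3 day 21 against day 0, miR-25-3p (−0.50), miR-127-3p (−0.77), miR-93-5p (−0.78), miR-541-5p (−1.06); for D3 day 21 against day 7, miR-127-3p (1.49), miR-292a-5p (1.21), miR-125b-5p (1.19), miR-541-5p (1.13), miR-99b-5p (0.55), miR-125a-5p (0.52), miR-25-3p (0.50), miR-293-3p (0.41), miR-295-3p (0.38), miR-128-3p (0.29), miR-93-5p (0.20), miR-92a-3p (0.10); for D3 against B8 at day 0, miR-541-5p (1.04), miR-127-3p (0.99), miR-410-3p (0.97), miR-375-3p (0.54), miR-192-5p (0.44), miR-1983 (0.10), miR-302a-3p (0.00949); for D3 against B8 at day 7, miR-219a-2-3p (−0.16), miR-1a-3p (−0.14), let-7a-5p (−0.75), miR-205-5p (−1.94), miR-141-3p (−2.09). With equal totals outside miR-10a and miR-10b the log2 values that changed sign were, for D3 day 7 against day 0, miR-302b-3p (−0.52), miR-541-5p (−0.66), miR-127-3p (−0.73), miR-302d-3p (−1.51), miR-302a-3p (−1.78). They were for D3 day 21 against day 0, miR-25-3p (−0.29), miR-127-3p (−0.57), miR-93-5p (−0.58), miR-541-5p (−0.85); for D3 against B8 at day 0, miR-541-5p (1.03), miR-127-3p (0.98), miR-410-3p (0.96), miR-375-3p (0.53), miR-192-5p (0.44), miR-1983 (0.10), miR-302a-3p (0.00207); for D3 against B8 at day 7, let-7a-5p (−0.0595), miR-205-5p (−1.25), miR-141-3p (−1.42). With edgeR and TMM factors the log2 values that changed sign were, for D3 day 7 against day 0, miR-302b-3p (−0.85), miR-541-5p (−0.98), miR-127-3p (−1.03), miR-302d-3p (−1.84), miR-302a-3p (−2.14). They were for D3 day 21 against day 0, miR-25-3p (−0.11), miR-127-3p (−0.40), miR-93-5p (−0.40), miR-541-5p (−0.70); for D3 day 21 against day 7, miR-127-3p (0.64), miR-541-5p (0.28); for D3 against B8 at day 0, miR-541-5p (0.79), miR-127-3p (0.72), miR-410-3p (0.70), miR-375-3p (0.31), miR-192-5p (0.21); for D3 against B8 at day 7, let-7a-5p (−0.33), miR-205-5p (−1.52), miR-141-3p (−1.71).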

Other observations

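The list tests of the interaction were chosen only after the results were seen; the splits of the samples were planned. Set against the other miRNAs, 5 lists differed in their change from day 0 to day 7 between the lines. Such a difference includes any gap at day 0, when the mesenchyme, let-7, and miR-99 and miR-125 lists were lower in D3. Mesenchyme miRNAs changed more in D3 in 13 of 13 cases (10 relative; camera adjusted p = 0.000134, and adjusted p = 0.337 with an estimated correlation), let-7 miRNAs in 14 of 15 (12 relative; adjusted p = 0.000682, and 0.337 with an estimated correlation) and miR-99 and miR-125 miRNAs in 9 of 9 (7 relative; adjusted p = 0.00116, and 0.237 with an estimated correlation). In the other direction were the Sfmbt2 cluster, with 11 of 42 members less positive in D3 (31 relative; adjusted p = 7.15e-34, and 0.00291 with an estimated correlation), and miR-290 cluster, with 1 of 13 less and 2 more positive as deposited but 11 less positive relative to the median (adjusted p = 6.37e-05, and 0.337 with an estimated correlation). The summed Sfmbt2 signal was 1660 ± 24.11 in B8 at day 0 and 1913 ± 150.8 at day 7, and in D3 950 ± 182.5 at day 0, 509.2 ± 8.627 at day 7 and 434.1 ± 86.08 at day 21 (SD, n = 3, and n = 2 for D3 at day 7). At day 0 it was already lower in D3 than in B8 (log2 −0.82 ± 0.22 SE, adjusted p = 0.0027; relative log2 0.23, adjusted p = 0.22). From day 0 to days 7 and 21 of D3 the sum fell by 0.88 ± 0.24 and 1.13 ± 0.22 (SE) on the log2 scale (limma adjusted p = 0.002 and 5e-05).

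With 3 samples against 3 there are 10 splits of the samples, too few for a share under 0.05. The real split of the B8 samples by day gave 260 miRNAs and the highest other split 1; for D3 at days 21 and 0 these were 393 and 0, and for D3 against B8 at day 0 they were 245 and 0. For lists, other splits gave as many or more in 2 of the comparisons. In B8 the real split gave 8 lists and another split 9, so that 2 of 10 splits, the real one included, gave as many. In D3 at days 21 and 0 the real split gave 8 and the highest other 9, with 3 of 10 splits as large. For D3 against B8 at day 0 the real split gave 11 lists and the highest other 5, so that 1 of 10 splits was as large.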
